A study of Rattus norvegicus with 14 samples.

How the data were processed

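Total RNA of plantaris muscle from 14 Wistar rats was extracted with Trizol, labelled with Cy3 and hybridised in 1 colour to Agilent rat arrays, 1 array per muscle. Per the file headers, the scanner files hold spot intensity from Agilent Feature Extraction 11.5.1.1 with protocol GE1_1105_Oct12, and the processed signal is background-subtracted and detrended within each array, with no scaling between arrays. The deposited series table holds 1 log2 value per probe made by the authors, normalized between arrays; per the submitters' processing notes Agilent Feature Extraction and limma were used, without a version for limma, and neither the filter nor the background correction is stated. That table holds 26902 probes with values from 5.662 to 19.423 and was used only as an alternative source.

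Each array held 44254 spots, of which 42877 were not controls. Spots marked as outliers by the scanner software (0.669% to 1.05% per array) were set to missing, spots of a probe were averaged, and log2 of the processed signal was taken relative to the array's 75th percentile. No spot was saturated. Of 30367 probes, 18438 were named by matching their accession to a RefSeq gene table, 3587 by symbol, 1820 kept the name in the file and 6522 had none, which gave 19769 symbols. Probe coordinates are those of the files, on rn4; only gene names came from the newer table. Probes were kept if well above background on at least 4 of 14 arrays with at least 2 values per group, which left 26387 probes of 17431 genes. A gene was represented by its brightest probe. Between 82.8% and 88.1% of spots per array were well above background; the mean net signal of the negative controls was 14.68 to 23.717, against a 75th percentile of 1781 to 2387.

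Arrays were grouped by title. The diet field of depletion replicate 1 contradicts its title, so results were also computed without it and with it counted as repletion. The 3 groups were fitted in 1 linear model with limma 3.58.1 in R 4.3.3, with moderated t tests and Benjamini-Hochberg adjustment over probes, and called at an adjusted p under 0.05. A set of 43 gene lists with at least 5 measured members was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over lists; camera with an estimated correlation and limma's fry served as stricter alternatives. Adjusted p values beside lists in the report are from camera and beside genes from limma's moderated t test. A list score is the mean over members of each array's deviation from the gene's mean. Lists share some members: Cd36 is in the slow fibre, fatty acid oxidation and adipocyte lists and Psmb9 in the interferon and antigen presentation lists. Pdk4 is in the fatty acid oxidation and tricarboxylic acid cycle lists. Shares of variance explained by slide and diet were tested with 100000 permutations of the arrays. Tables were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.

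The groups, comparisons, gene lists, naming rule and main alternatives were fixed before the data were examined. The naming rule took up to 12 genes per direction past the threshold, or else filled to 5 by smallest unadjusted p, with 4 members of each passing list and 20 genes of vitamin D, Notch, atrophy, fat and fibre biology. It named 142 genes, of which the report gives a part; some single-gene results, withheld for evaluation, are not reported here and were left out of the search for arrays that stand apart. By the naming rule, 1 predicted locus was left out in depletion against control and 1 in repletion against control. No probe of Cyp24a1 or Cyp2r1 passed the filter.

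Alternatives were normexp background correction (offset 50), quantile normalization, median centring, the authors' values, no filter and a filter on all 14 arrays, outlier-marked spots kept, slide as a fixed or random block, replicate number as a block, array weights, fits of only the groups compared, the mean of a gene's probes, and each array left out in turn. Settings without slide 2, without slides 2 and 3, slide block with depletion replicate 1 removed or moved, the authors' values with slide block, and slide block with the stricter list tests were added after the data were seen, as were an exact permutation test of list scores and splits of the labels within slides. The fit was tested on simulated data over 26078 probes, with 50 probes per fold change planted in each comparison. With slide effects as fitted in these data, 2-fold changes were recovered at 46%, 38% and 34% without a block and at 52%, 68% and 44% with slide as a block, in the order of the report. For 1.5-fold changes the recovery was 8%, 12% and 2% without a block and 16%, 16% and 8% with it, so changes of that size would mostly be missed. A planted log2 shift of 0.3 in the slow fibre list was called by camera (adjusted p = 6.76e-07) with 0 other lists called. That simulation drew genes and arrays independently, without slide effects. It therefore does not show how often camera calls unchanged lists in these arrays. Exon and untranslated-region annotation was not used here.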

Results

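Gene expression was measured in plantaris, a fast-twitch calf muscle, from Wistar rats on 3 diets. Control rats (n = 4) ate a diet with 1000 IU of vitamin D per kg. Depletion rats (n = 6) ate a diet depleted of vitamin D, and repletion rats (n = 4) ate a depleted diet followed by one with vitamin D restored. The vitamin D content of the depleted and restored diets and the length of feeding are not given in the sources used here. Each of the 14 muscles was hybridised in 1 colour to 1 array, and the titles call the muscles biological replicates. The diet field of depletion replicate 1 names the repletion diet, against its title, so its group is in doubt; it was kept as depletion. Levels are log2 signals relative to the 75th percentile of the same array, so 0 is a bright probe and each unit is a doubling. Group levels are given as mean ± SD and differences as log2 difference ± SE from limma's fit. Between 82.8% and 88.1% of the spots of an array were well above background, and the 75th percentile of the signal lay between 1781 and 2387. The number of arrays limits the precision.

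Muscles resembled one another by array slide more than by diet. Slide 1 held control replicates 1 and 2, repletion replicate 1 and depletion replicate 1, and slide 2 held replicate 3 of control with replicate 2 of both other diets. Slide 3 held repletion replicate 3 with depletion replicates 3 and 4, slide 4 held control replicate 4 with depletion replicate 5, and slide 5 held repletion replicate 4 with depletion replicate 6. The first principal component held 39.1% of the variance, of which slide explained a share of 0.996 (permutation p = 1e-05, the smallest that 100000 permutations can give). Diet explained a share of 0.017 of it (permutation p = 0.925). With diet in the model, limma's F test called 7358 of 26078 probes different between slides at an adjusted p under 0.05. The same F test for diet called 0 of them, with or without slide in the model. Values with slide as a block, and within slides that held both diets, are therefore given beside the main differences of the lists that passed. For single genes such values are given only in part, and most gene differences below are not set against slide.

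**Figure D1:**
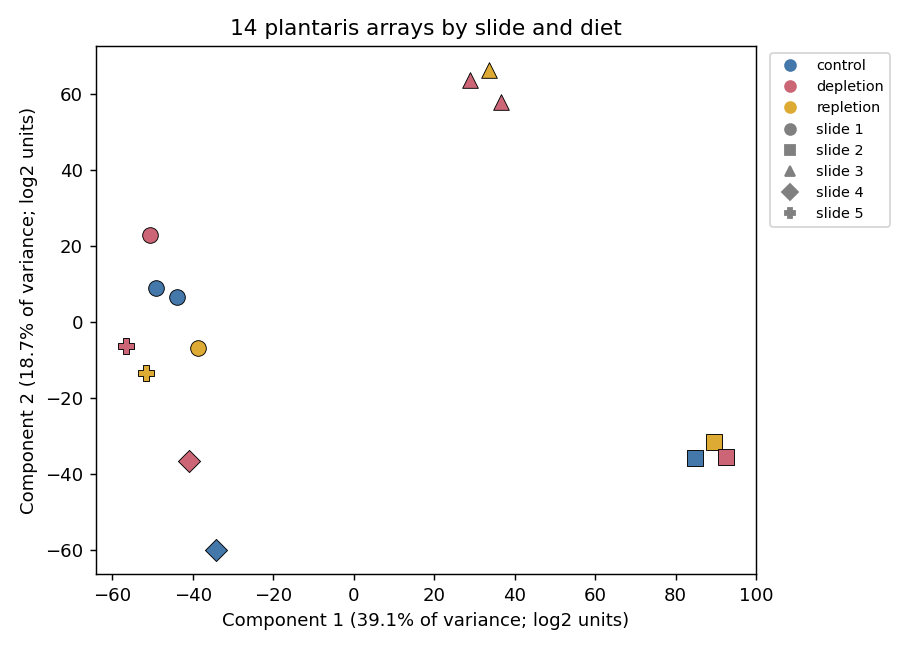
Position of the 14 arrays on the first and second principal components of the log2 signals, with 39.1% and 18.7% of the variance on the axes. Colour marks the diet and shape the slide; arrays of 1 slide lie together whatever their diet, and slides explain a share of 0.996 of the first component.

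The comparison of depletion with control asked what a lack of dietary vitamin D did to muscle transcripts. As a group, genes of slow oxidative fibres were higher after depletion, with all 18 measured members above control and a median log2 difference of 0.54. All 55 measured ribosomal protein genes were also higher, by a median of 0.18, and so were 22 of 24 immediate early genes, by a median of 0.33. Glycolysis and glycogen genes were lower, by a median of -0.25, with 22 of 26 members below control. With an estimated correlation none of these 4 lists passed, the camera adjusted p being 0.318 for the first 3 and 0.577 for glycolysis. No single gene passed the test: limma called 0 of 26387 probes at an adjusted p under 0.05 (lowest adjusted p 0.999). At an unadjusted p under 0.05, 402 were higher and 573 lower. These 975 are below the share of 0.05 of the probes that unchanged probes give on average.

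Among the genes with the smallest unadjusted p, none of which passes, 1 of those higher than in control was Fos, a transcription factor induced within minutes of stimulation. Its level was 1.36 ± 0.53 after depletion (n = 6) and -0.15 ± 0.41 in control (n = 4). The difference was 1.51 ± 0.29, with limma's adjusted p at 0.999. The probe lies on chromosome 6 at 109561941 to 109562000 (rn4, as the array files give it). All 6 depletion arrays lay above the control mean, and the within-slide differences on slides 1, 2 and 4 were 1.53, 0.76 and 0.84. Gnat3, a G protein subunit of taste cells, was higher by 1.62 ± 0.36 at a low level (chromosome 4, 12785440 to 12785500), but by 0.49 with normexp and 0.75 on the authors' values. Lzts1 was higher by 0.87 ± 0.19, Ttc9 by 0.71 ± 0.17, and Hnrnpa1, an RNA-binding splicing factor, by 0.69 ± 0.15, though its other probe gave 0.20. Lower in depletion were Trit1, a tRNA-modifying enzyme (-0.66 ± 0.13), Birc6, an inhibitor of apoptosis (-0.78 ± 0.18), and Nipal2 (-0.60 ± 0.15). Lpcat1, which acylates lysophosphatidylcholine, was lower too, but was well above background on 1 of 6 depletion arrays, so no size is given. Or5b106, an olfactory receptor, was not well above background on any depletion array. All 4 control arrays gave a value, and control replicate 3 was the lowest at -7.98 (nearest other -6.12). On the values used here Or5b106 was at least 2.12-fold lower after depletion. The bound sets the control mean, control replicate 3 included, against a floor. That floor is the lowest signal well above background on each depletion array or the probe's own, whichever was higher. The probe lies on chromosome 1 at 216365175 to 216365234, and the bound does not hold with normexp, where the difference was -0.72.

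The slow fibre list held sarcomere, calcium pump and lipid uptake genes. Myh7, the slow myosin heavy chain, was at 7.23 ± 0.35 after depletion (n = 6) and 6.52 ± 0.33 in control (n = 4), a difference of 0.71 ± 0.25 (chromosome 15, 33073880 to 33073939). Atp2a2, the slow-fibre and cardiac calcium pump, was higher by 0.91 ± 0.32. Tnnt1, slow troponin T, was higher by 0.43 ± 0.16, and Cd36, a fatty acid transporter, by 0.39 ± 0.13. Of the 18 members, 7 had an unadjusted p under 0.05, and 0 passed when adjusted over the list alone or over all probes. The list passed limma's camera test with its preset inter-gene correlation (adjusted p = 9.53e-14), but not with an estimated correlation (adjusted p = 0.318). Its score, the mean deviation of the members, was above the control mean on 6 of 6 depletion arrays. With slide as a block its median was 0.54, and within slides 1, 2 and 4 it was 0.83, -0.17 and 0.61.

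Ribosomal protein genes were higher by small, even amounts, and their call too was lost with an estimated correlation. Rps7 was higher by 0.34 ± 0.09, Rps24 by 0.30 ± 0.11 and Rps21 by 0.26 ± 0.10. In the list, 9 of 55 members had an unadjusted p under 0.05, the adjusted p was 3.43e-24, and it was 0.318 with an estimated correlation. Within slides 1, 2 and 4 the median was 0.33, 0.02 and 0.17, and with slide as a block 0.19. The score was above the control mean on 5 of 6 depletion arrays. Among immediate early genes, the antiproliferative gene Btg2 was higher by 0.85 ± 0.24, the matricellular gene Ccn1 by 0.82 ± 0.37 and Fosl2 by 0.33 ± 0.15. Fosl2 differed by 0.10 with normexp and 0.22 on the authors' values, and Ccn1 by 1.41 without slide 2. In this list 2 genes passed when adjusted over the list alone, and 0 over all probes. Its adjusted p was 4.33e-08, and 0.318 with an estimated correlation. The median was 0.27 with slide as a block, and 0.10, -0.13 and 0.56 within slides 1, 2 and 4.

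Several immune and blood cell lists were higher after depletion as groups. The lists of T and NK cells, B and plasma cells, and neutrophils and mast cells did not pass. The interferon response list (28 genes, median 0.24, 22 higher) included Rsad2, an antiviral protein, at 0.98 ± 0.40, the chemokine Cxcl10 at 1.12 ± 0.55 and the immunoproteasome subunit Psmb9 at 0.29 ± 0.12. The cytokine and NF-kB list (28 genes, median 0.27, 23 higher) included Cxcl1 at 0.85 ± 0.26, Ccl3 at 1.21 ± 0.46, Il1b at 0.81 ± 0.39 and the adaptor Myd88 at 0.46 ± 0.15. With normexp Cxcl10 was at 0.54, Cxcl1 at 0.10, Ccl3 at 0.12 and Il1b at 0.20, and on the authors' values they were at 0.71, 0.40, 0.33 and 0.35. Cxcl10 was at 0.66 without depletion replicate 5, the highest of the 6 depletion arrays. Both lists had a camera adjusted p of 7.48e-05, and 0.387 with an estimated correlation. Macrophage markers were higher too, by a median of 0.20 (20 of 23 members; Aif1 0.47 ± 0.23, Lyz2 0.46 ± 0.36), with an adjusted p of 0.0157 and 0.831 with an estimated correlation. Their score spanned -0.73 to 0.69 over the 6 depletion arrays, and was above the control mean on 4 of them. Antigen presentation genes were higher by a median of 0.14 (15 of 20; Tap2 0.60 ± 0.22, B2m 0.37 ± 0.18, adjusted p = 0.0157, and 0.461 with an estimated correlation). Red blood cell genes were higher by a median of 0.50 (6 of 8; adjusted p = 0.0281, and 0.461 with an estimated correlation), with the globin gene Hbb at 0.70 ± 0.33 and the erythroid haem synthesis enzyme Alas2 at 0.81 ± 0.40. Without depletion replicate 1, the array of doubtful label, Alas2 was at 0.51 and B2m at 0.24. Lyz2 was at 0.71 and 0.20 without control replicates 3 and 4, B2m at 0.15 on the authors' values and Hbb at 0.44 with array weights. Over all settings B2m ran from 0.021 to 0.53. In the fit with slide as a block, the medians of these 5 lists were 0.30, 0.35, 0.48, 0.20 and 0.47. With normexp the cytokine median was 0.07 and the red blood cell median 0.14. With replicate number as a block the red blood cell median was 0.80. Within slides 1, 2 and 4 the interferon list gave -0.10, 0.39 and 0.61, the cytokine list 0.45, 0.05 and 0.44, macrophages 0.76, 0.51 and 0.44, antigen presentation 0.40, 0.30 and 0.34, and red blood cells 1.05, 0.49 and 0.21. The interferon, antigen presentation and red blood cell scores were above the control mean on 5 of 6 depletion arrays, and the cytokine score on 4.

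Genes of energy metabolism differed in both directions. Pkm, muscle pyruvate kinase, was lower by -0.66 ± 0.22, Pgm1 by -0.32 ± 0.16 and glycogenin Gyg1 by -0.24 ± 0.10. The glycolysis and glycogen list had an adjusted p of 0.000143, and 0.577 with an estimated correlation; its within-slide medians were -0.32, -0.05 and -0.52. Pyruvate dehydrogenase and tricarboxylic acid cycle genes were lower by a median of -0.11 (20 of 26 members; adjusted p = 0.00732, and 0.831 with an estimated correlation), with Idh3a at -0.35 ± 0.14, Dlat at -0.30 ± 0.16 and the dehydrogenase kinases Pdk4 and Pdk2 at -0.46 ± 0.21 and -0.35 ± 0.16. The kinases inhibit the dehydrogenase that Dlat belongs to. Pdk4 is also a member of the fatty acid oxidation list, which as a group was slightly higher. Mitochondrial biogenesis and dynamics genes were lower by a median of -0.07 (20 of 26; adjusted p = 0.0157, and 0.461 with an estimated correlation). Ppargc1a, a master coactivator of mitochondrial biogenesis, was lower by -0.63 ± 0.26, the polymerase Polg by -0.31 ± 0.15, and the fusion genes Mfn1 and Opa1 by -0.28 ± 0.12 and -0.19 ± 0.10. Fatty acid oxidation genes were slightly higher (median 0.07, 20 of 30; adjusted p = 0.0346, and 0.831 with an estimated correlation), with Acot2 at 0.36 ± 0.15, Decr1 at 0.34 ± 0.19 and Cpt1b at 0.20 ± 0.10. Genes of the neuromuscular junction and of denervation were higher by a median of 0.41 (18 of 24; adjusted p = 0.000415, and 0.387 with an estimated correlation). They included the acetylcholine receptor subunits Chrnd (0.85 ± 0.25), Chrna1 (0.94 ± 0.41) and the embryonic Chrng (1.06 ± 0.49), and Etv5 (0.46 ± 0.20). Their within-slide medians were -0.04, -0.13 and 0.99. Within slides 1, 2 and 4 the tricarboxylic acid cycle list gave -0.42, -0.02 and 0.03, the mitochondrial list -0.23, -0.08 and -0.06, and fatty acid oxidation -0.07, 0.14 and 0.01. After blocking on slide, the medians were -0.21 for glycolysis, -0.14 for the tricarboxylic acid cycle, -0.06 for the mitochondrial list, 0.06 for fatty acid oxidation and 0.21 for the junction. The scores lay on the side of these medians on 5, 4, 6, 4 and 5 of 6 depletion arrays. Single arrays carried part of several gene differences: Ppargc1a was at -0.30 without control replicate 1, Dlat at -0.19 without control replicate 2 and Polg at -0.18 without control replicate 3. Without control replicate 4 Pdk2 was at -0.23 and Chrna1 at 0.54, and Chrng was at 0.70 without depletion replicate 6. With slide as a block Chrng was at 0.59 and Pdk4 at -0.30. On the authors' values Ppargc1a was at -0.42 and Mfn1 at -0.17, and Dlat was at -0.17 with normexp, Decr1 at 0.19 with array weights and Etv5 at 0.21 without slide 2. Over all settings Cpt1b ran from 0.024 to 0.244.

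No vitamin D gene passed the test. Vdr, the vitamin D receptor, was at -4.21 ± 0.71 after depletion (n = 6) and -4.06 ± 0.71 in control (n = 4), a difference of -0.15 ± 0.41 (chromosome 7, 136567655 to 136567714). Cyp27b1, which makes the active hormone, differed by -0.01 ± 0.27, and no probe of Cyp24a1 or Cyp2r1 passed the filter on dim probes. The list of 13 vitamin D metabolism and receptor genes had a median of -0.11 (camera adjusted p = 0.411). Notch1 differed by 0.18 ± 0.14, and its targets Hey1 and Hes1 by 0.01 ± 0.80 and 0.09 ± 0.25. The ubiquitin ligases of muscle atrophy Fbxo32 and Trim63 differed by -0.40 ± 0.22 and -0.15 ± 0.36, and myostatin, Mstn, by -0.36 ± 0.30. Fat cell genes Adipoq, Fabp4 and Plin1 differed by -0.02 ± 0.56, 0.02 ± 0.16 and -0.37 ± 0.55. Fast myosins Myh1, Myh2 and Myh4 differed by 0.07 ± 0.14, -0.09 ± 0.37 and -0.28 ± 0.39. With single arrays left out in turn, the sign turned for Vdr (-0.39 to 0.18), Cyp27b1 (-0.19 to 0.17), Hey1 (-0.30 to 0.57), Hes1 (-0.06 to 0.27), Trim63 (-0.30 to 0.05), Adipoq (-0.48 to 0.53), Fabp4 (-0.10 to 0.10), Myh1 (-0.05 to 0.15) and Myh2 (-0.28 to 0.13). It did not for Notch1 (0.11 to 0.29), Mstn (-0.55 to -0.21), Plin1 (-0.88 to -0.09), Myh4 (-0.52 to -0.03) and Fbxo32 (-0.55 to -0.31).

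In all, 13 of the 43 lists passed in this comparison, 10 higher and 3 lower, and 0 with an estimated correlation. The split was 16 higher and 0 lower with normexp background correction, 9 and 6 with quantile normalization, and 7 and 4 on the authors' values. With normexp the median difference of all probes was -0.15, and the call ended for glycolysis (camera adjusted p = 0.125), the tricarboxylic acid cycle (0.860) and the mitochondrial list (0.351). Blocking on slide, the calls of the junction (camera adjusted p = 0.0942), mitochondrial (0.121) and fatty acid oxidation lists (0.216) ended. Leaving out single arrays also ended calls. Without depletion replicate 1, adjusted p was 0.419 for the tricarboxylic acid cycle, 0.0541 for antigen presentation, 0.510 for macrophages and 0.0880 for red blood cells. Without control replicate 4 it was 0.0563 for the junction list, 0.114 for fatty acid oxidation, 0.141 for antigen presentation, 0.427 for macrophages and 0.0821 for red blood cells. Without depletion replicate 2 it was 0.374 for fatty acid oxidation, 0.209 for macrophages and 0.148 for red blood cells. The remaining single-array losses were fatty acid oxidation without control replicate 1 (0.275) or depletion replicate 6 (0.126), and without control replicate 2 the tricarboxylic acid cycle (0.172), mitochondrial (0.124) and red blood cell lists (0.0763). Antigen presentation was also lost without control replicate 3 (0.0876) or depletion replicate 5 (0.0514), the mitochondrial list without depletion replicate 5 (0.0708), macrophages without depletion replicate 4 (0.163) and red blood cells without depletion replicate 3 (0.0773).

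Other settings ended calls of the same 8 lists. Array weights ended macrophages (camera adjusted p = 0.592), antigen presentation (0.311) and red blood cells (0.198). The authors' values ended fatty acid oxidation (0.2998), and antigen presentation and red blood cells (0.0548 each). Fatty acid oxidation also ended with quantile normalization (0.510), slide as a random block (0.0618) and the mean of a gene's probes (0.0823). With replicate number as a block the junction (0.0599), fatty acid oxidation (0.0719) and mitochondrial lists (0.0700) were lost. Depletion replicate 1 counted as repletion ended the tricarboxylic acid cycle (0.393), antigen presentation (0.0562), macrophages (0.470) and red blood cells (0.209). Of 33 settings with the preset correlation, the call ended under 13 for fatty acid oxidation, 12 for red blood cells, 10 for the mitochondrial list, 9 for antigen presentation, 8 for macrophages, 6 each for the junction and the tricarboxylic acid cycle, and 2 for glycolysis. The exact permutation test of list scores gave p = 0.0286 for slow fibre and mitochondrial genes, or 0.546 adjusted over lists. No list had a lower adjusted p in this comparison, so none of the lists called by camera passed the exact test. The unadjusted p of the exact test was 0.152 for the junction, 0.181 for glycolysis, 0.248 for the tricarboxylic acid cycle and 0.552 for fatty acid oxidation.

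The size of several called medians also hung on 1 array. The junction median of 0.41 fell to 0.12 without control replicate 4, 0.25 without control replicate 2 and 0.26 without depletion replicate 5. Fatty acid oxidation (0.07) was at 0.02 without control replicate 1, 0.05 without depletion replicate 2 and 0.14 without control replicate 3. The tricarboxylic acid cycle (-0.11) was at -0.03 without depletion replicate 1, glycolysis (-0.25) at -0.15 without control replicate 4 and the mitochondrial list (-0.07) at -0.14 without control replicate 1. Immediate early genes (0.33) were at 0.22 without control replicate 4 and interferon genes (0.24) at 0.12 without depletion replicate 5. Antigen presentation (0.14) was at 0.07 without control replicate 4, 0.09 without depletion replicate 1 and 0.08 without depletion replicate 2. Macrophages (0.20) were at 0.13, 0.11, 0.39 and 0.38 without depletion replicates 1, 2, 3 and 6, and at 0.31 without control replicate 3.

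**Figure D2:**
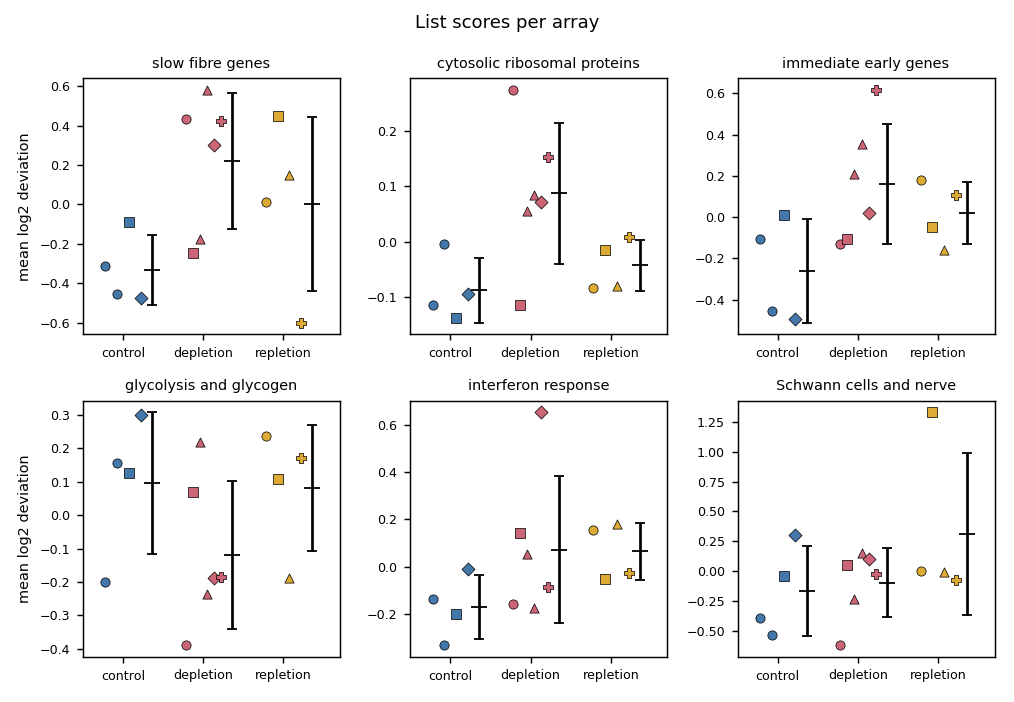
Score of 6 gene lists on each array, in log2 units as the mean deviation of the list's members from their mean over 14 arrays; colour marks the diet, shape the slide, and bars the mean ± SD of a group. Slow fibre scores average 0.22 in depletion, -0.33 in control and 0.00 in repletion, and the highest Schwann cell and nerve score, 1.33, is that of repletion replicate 2.

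The comparison of repletion with depletion asked whether restoring dietary vitamin D moved muscle transcripts away from the depleted level. Several groups that were higher after depletion were lower here: slow fibre genes by a median of -0.18 (18 of 18 members lower), ribosomal protein genes by -0.13 (55 of 55 lower) and immediate early genes by -0.15 (14 of 24 lower). Glycolysis and glycogen genes were higher, by a median of 0.21 (23 of 26), and Schwann cell and nerve genes were higher by 0.37 (17 of 20). With an estimated correlation none of these 5 lists passed, with a camera adjusted p of 0.575 for each. No single gene passed: limma called 0 of 26387 probes at an adjusted p under 0.05 (lowest adjusted p 1.00), with 273 higher and 107 lower at an unadjusted p under 0.05. These 380 too are below the share of 0.05 of the probes that unchanged probes give on average. The depletion arrays enter both comparisons, so opposite signs are favoured by construction.

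Of the genes with the smallest unadjusted p, Tppp2, a tubulin polymerization-promoting protein, was lower in repletion. Its level was -2.08 ± 0.23 (n = 4) against -0.36 ± 0.65 in depletion (n = 6), a difference of -1.72 ± 0.36 with limma's adjusted p at 1.00 (chromosome 15, 27354011 to 27354070). The difference was -1.44, -1.83, -1.82 and -1.26 within slides 1, 2, 3 and 5, and 4 of 4 repletion arrays lay below the depletion mean. Also lower were the cell cycle gene Cks2 (-1.04 ± 0.32), the retinoic acid hydroxylase Cyp26b1 (-0.90 ± 0.26), Tspo2 (-0.74 ± 0.23) and Stam2 (-0.26 ± 0.08). Higher were Birc6 (0.79 ± 0.18), the vessel growth factor Angpt1 (0.67 ± 0.15), Trit1 (0.54 ± 0.13) and Cox11, a cytochrome oxidase assembly factor (0.48 ± 0.13, with another of its probes at 0.06). Tspo2 differed by -0.14 with normexp and -0.10 on the authors' values, and Stam2 by -0.14 and -0.15. Tspo2 was also at -0.49 without repletion replicate 2. With depletion replicate 1 counted as repletion Cks2 was at -0.55, Cyp26b1 at -0.55 and Tspo2 at -0.48, and Cox11 was at 0.28 without slides 2 and 3. Lpcat1 was higher too, but was well above background on 1 of 6 depletion and 2 of 4 repletion arrays, so no size is given. Birc6, Trit1 and Lpcat1 were named as lower in depletion against control as well, and share the depletion arrays with it.

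Among the groups, slow fibre members with the smallest p were Ankrd2 (-0.79 ± 0.40), Csrp3 (-0.38 ± 0.37), Pln (-0.23 ± 0.17) and Cd36 (-0.20 ± 0.13), and Myh7 differed by -0.17 ± 0.25, and by 0.07 without repletion replicate 4. The slow fibre list had a camera adjusted p of 0.000215, and 0.575 with an estimated correlation; its medians within slides 1, 2, 3 and 5 were -0.41, 0.84, -0.05 and -1.002. Ribosomal proteins had an adjusted p of 5.25e-21, and 0.575 with an estimated correlation, with Rps7 at -0.25 ± 0.09 and Rplp0 at -0.16 ± 0.09. Their within-slide medians were -0.34, 0.09, -0.15 and -0.13. Glycolysis (adjusted p = 6.79e-05, and 0.575 with an estimated correlation) included Gpd1 at 0.57 ± 0.30, the lactate transporter Slc16a3 at 0.45 ± 0.26 (-0.02 with depletion replicate 1 counted as repletion) and Pkm at 0.39 ± 0.22, and its within-slide medians were 0.61, 0.02, -0.20 and 0.43. Immediate early genes (adjusted p = 0.00702, and 0.575 with an estimated correlation) included Fos at -0.86 ± 0.29, Egr1 at -1.06 ± 0.55, Btg2 at -0.45 ± 0.24 and Junb at -0.46 ± 0.25; within slides they gave 0.15, 0.02, -0.33 and -0.27. In the fit with slide as a block, the medians of these 4 lists were -0.20, -0.14, 0.23 and -0.14. The ribosomal score was below the depletion mean on 4 of 4 repletion arrays, and each of the other 3 scores lay on the side of its median on 3 of 4. Gene values moved with single arrays: Cd36 was at -0.12 without repletion replicate 2 and -0.13 without depletion replicate 1, Pln at -0.15 without repletion replicate 1, and Csrp3 at -0.23 without repletion replicate 4 and -0.24 without depletion replicate 5. Myh7 was at -0.35 without repletion replicate 2 and at -0.11, -0.27 and -0.09 without depletion replicates 1, 2 and 4. Slc16a3 was at 0.26 without depletion replicate 1 and Egr1 at -0.68 without depletion replicate 6. With depletion replicate 1 counted as repletion Ankrd2 was at -0.38, Csrp3 at -0.14, Gpd1 at 0.10, Pkm at 0.10 and Junb at -0.26. Without slides 2 and 3 Fos was at -0.36 and Btg2 at -0.07.

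Schwann cell and nerve genes rested on repletion replicate 2. The myelin gene Mbp was higher by 1.37 ± 0.74, the myelin gene Prx by 0.87 ± 0.34 and the sodium channel Scn7a by 0.57 ± 0.30; the other probe of Mbp gave -0.06. The list had an adjusted p of 0.00104, and 0.575 with an estimated correlation, and its medians within slides 1, 2, 3 and 5 were 0.49, 1.25, 0.01 and 0.12. Without repletion replicate 2 its median was 0.08 and its adjusted p 0.418, and Mbp was at 0.44, Prx at 0.39 and Scn7a at 0.20. Scn7a was at 0.86 without repletion replicate 4. With depletion replicate 1 counted as repletion Mbp was at 0.74 and Scn7a at 0.33, and Prx was at 0.55 with normexp and 0.54 on the authors' values. After blocking on slide, the median was 0.39, and all 4 repletion scores were above the depletion mean.

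The other lists that passed shifted by smaller amounts. Cytokine and NF-kB genes were lower by a median of -0.19 (adjusted p = 0.0029, and 0.575 with an estimated correlation), with Cxcl1 at -0.65 ± 0.26, Tnf at -0.52 ± 0.34 and Myd88 at -0.29 ± 0.15. Heat shock protein genes were lower by -0.07 (adjusted p = 0.00846, and 0.658 with an estimated correlation), with Hspa1b at -0.70 ± 0.52 and Dnajb1 at -0.56 ± 0.34. Antigen presentation genes were lower by -0.08 (0.00872, and 0.575 with an estimated correlation), with Tap1 at -0.29 ± 0.18 and RT1-Db1 at -0.79 ± 0.54. Neuromuscular junction genes were lower by -0.19 (0.0184, and 0.589 with an estimated correlation), with sarcolipin, Sln, at -0.66 ± 0.36 and Chrna1 at -0.71 ± 0.41. Endothelial genes were lower by -0.06 (0.0422, and 0.677 with an estimated correlation), with Pecam1 at -0.30 ± 0.12 and Kdr at -0.21 ± 0.14. Mitochondrial biogenesis genes were higher by 0.07 (0.00872, and 0.575 with an estimated correlation), with the kinase subunit Prkaa2 at 0.27 ± 0.13 and Esrrg at 0.34 ± 0.17. Fast fibre genes were higher by 0.10 (0.0315, and 0.754 with an estimated correlation), with Mybpc2 at 0.39 ± 0.26 and Pvalb at 0.30 ± 0.22, the latter at -0.14 with depletion replicate 1 counted as repletion. Within slides 1, 2, 3 and 5 the cytokine list gave -0.40, -0.07, -0.01 and 0.09, heat shock 0.17, 0.07, -0.20 and -0.38, and antigen presentation -0.41, -0.13, -0.28 and 0.47. The junction list gave -0.59, 0.09, -0.12 and -0.01, the mitochondrial list 0.40, 0.01, 0.00 and 0.02, and fast fibres 0.44, 0.08, -0.22 and 0.09. Endothelial genes gave 0.02, -0.31, 0.10 and 0.04. Slide as a block gave -0.12, -0.10, -0.06, -0.25, 0.00, 0.06 and 0.10 for these 7 lists in the order first named. On all 4 repletion arrays the cytokine and heat shock scores were below the depletion mean, and the other 5 scores lay on the side of their medians on 3 of 4. Vdr differed by 0.13 ± 0.41, Cyp27b1 by -0.01 ± 0.27, Notch1 by -0.16 ± 0.14, Hey1 by 0.32 ± 0.80, Fbxo32 by 0.22 ± 0.22 and Adipoq by -0.11 ± 0.56. With single arrays left out in turn these ran from -0.13 to 0.43, -0.20 to 0.10, -0.23 to -0.03, -0.20 to 0.81, 0.12 to 0.33 and -0.28 to 0.24.

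Single arrays also moved the genes named from these 7 lists. Only 2 of 4 repletion arrays lay below the depletion mean for RT1-Db1, which was at -0.45, -0.34 and -1.21 without repletion replicates 1, 3 and 4. Hspa1b was at -0.40 without depletion replicate 4, Dnajb1 at -0.35 without depletion replicate 6, Tnf at -0.26 without repletion replicate 4 and Sln at -0.41 without repletion replicate 1. Without repletion replicate 3 Tap1 was at -0.18, Kdr at -0.33 and Mybpc2 at 0.63, and without repletion replicate 4 Kdr was at -0.10. Without depletion replicate 1 Myd88 was at -0.19 and Pvalb at 0.11, and Esrrg was at 0.22 and 0.52 without repletion replicates 2 and 4. With depletion replicate 1 counted as repletion Cxcl1 was at -0.36, Tnf at -0.20, Myd88 at -0.04, Tap1 at -0.10, Sln at -0.32, Chrna1 at -0.44 and Mybpc2 at 0.20, while Dnajb1 was at -0.87 and Hspa1b at -1.19. With normexp Esrrg was at 0.11, Cxcl1 at -0.30 and Tnf at -0.31. Slide as a block put Kdr at -0.13.

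**Figure D3:**
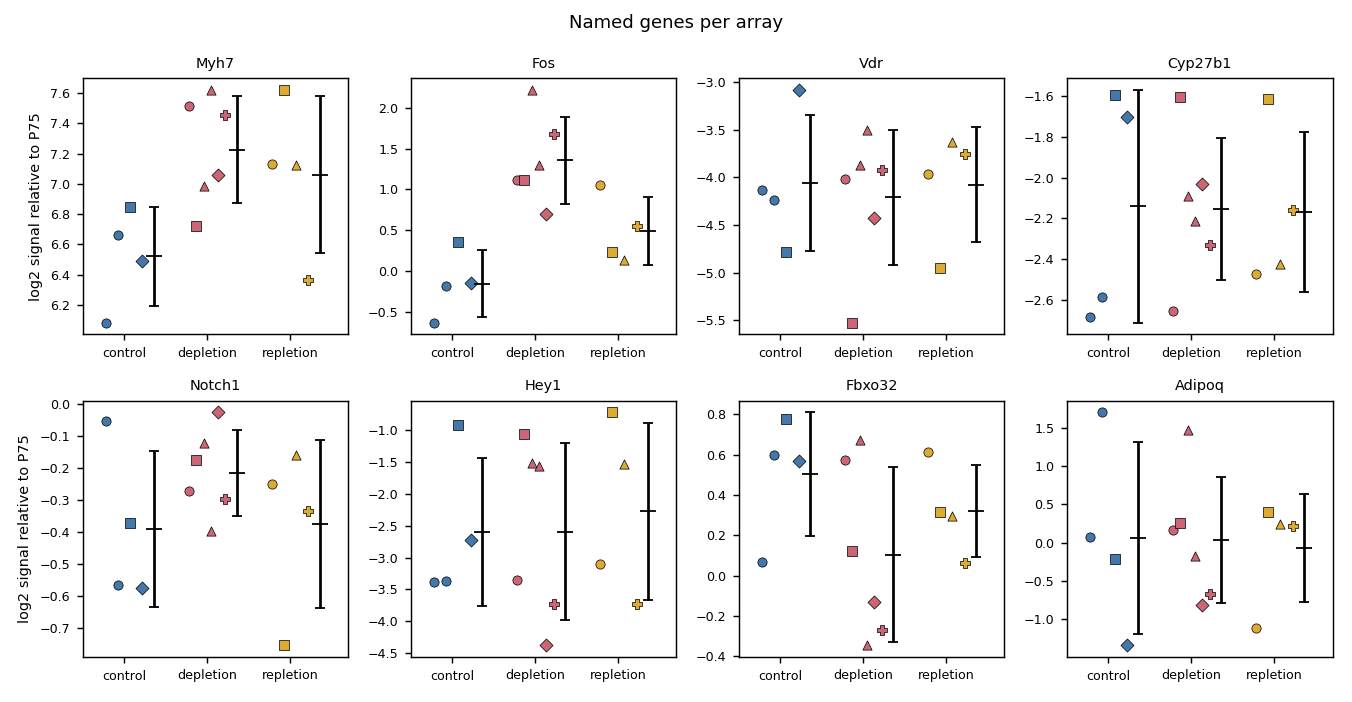
Level of 8 genes fixed or ranked for naming on each array, as log2 signal relative to the array's 75th percentile; colour marks the diet, shape the slide, and bars the mean ± SD of a group. Fos averages 1.36 in depletion and -0.15 in control, while Vdr averages -4.21 and -4.06.

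In this comparison 12 of 43 lists passed, 4 higher and 8 lower, and 0 with an estimated correlation. The split was 7 and 8 with normexp, 6 and 8 with quantile normalization or on the authors' values. Blocking on slide, the calls of fast fibres (camera adjusted p = 0.173), the mitochondrial list (0.106) and endothelial genes (0.205) ended. Counting depletion replicate 1 as repletion, as its diet field says, ended the call of slow fibres (0.280), glycolysis (0.380), ribosomal proteins (0.115), cytokines (0.870), antigen presentation (0.420), Schwann cells (0.420), the junction (0.0644), the mitochondrial list (0.119) and fast fibres (0.473), the last with a median of -0.04. With that array counted as repletion 10 lists passed, of which only 3 were among those of the main fit. Lists called anew included OXPHOS complex I (median -0.175, camera adjusted p = 3.82e-13) and proteasome genes (0.133, 1.56e-08). The tricarboxylic acid cycle was called anew as well (-0.105, 0.00376). Without repletion replicate 4 the slow fibre median was 0.01 (camera adjusted p = 0.428). Without repletion replicate 2, adjusted p was 0.233 for immediate early genes, 0.0504 for cytokines, 0.0580 for antigen presentation, 0.0820 for heat shock, 0.139 for the junction, 0.0520 for fast fibres and 0.843 for endothelial genes. Without depletion replicate 4 it was 0.0530 for immediate early, cytokine and mitochondrial genes alike, 0.284 for heat shock, 0.0722 for the junction, 0.0634 for fast fibres and 0.0556 for endothelial genes. Without repletion replicate 1 it was 0.460 for fast fibres, 0.336 for the junction and 0.318 for the mitochondrial list, and without depletion replicate 6 it was 0.203 for immediate early genes, 0.172 for the junction and 0.0605 for heat shock. Without depletion replicate 1 it was 0.0918 for cytokines and 0.317 for fast fibres, and without repletion replicate 4 also 0.144 for heat shock, 0.360 for fast fibres and 0.0916 for endothelial genes. Immediate early genes were lost without repletion replicate 3 (0.0771), fast fibres and endothelial genes without depletion replicate 2 (0.194 and 0.116), and endothelial genes without depletion replicates 3 or 5 (0.101 and 0.345), in the last case with a median of 0.02.

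Further settings bore on the same calls. Without slides 2 and 3 the immediate early median was 0.03 (camera adjusted p = 0.433), of the opposite sign, and with replicate number as a block that list was lost as well (0.162). The same block ended the junction (0.362), heat shock (0.128) and endothelial lists (0.145). Array weights ended Schwann cells (0.367), endothelial genes (0.241), antigen presentation (0.0877) and fast fibres (0.0516). Fast fibres also ended with median centring (0.0554) and slide as a random block (0.0605), and endothelial genes with that block (0.109) and without a filter on dim probes (0.0507). Of 33 settings with the preset correlation, the call ended under 15 each for fast fibres and endothelial genes, 8 for the junction, 7 each for the mitochondrial, heat shock and antigen presentation lists, and 6 each for immediate early genes and cytokines. It ended under 5 for Schwann cells, 3 each for slow fibres and glycolysis, and 1 for ribosomal proteins.

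Single arrays moved most of these medians. Slow fibres (-0.18) were at -0.35 without repletion replicate 2, and at -0.12, -0.29 and -0.11 without depletion replicates 1, 2 and 4. Immediate early genes (-0.15) were at -0.09 and -0.05 without depletion replicates 4 and 6. Fast fibres (0.10) were at 0.06 and 0.17 without repletion replicates 1 and 3, and at 0.05 without depletion replicate 1. The junction list (-0.19) was at -0.06 without repletion replicate 1 and -0.32 without depletion replicate 2, and glycolysis (0.21) at 0.33 without repletion replicate 3. The mitochondrial list (0.07) was at 0.05 and 0.11 without repletion replicates 1 and 3. Heat shock genes (-0.07) were at -0.15 without repletion replicate 1, and at -0.16, -0.11 and -0.02 without depletion replicates 2, 3 and 4. Cytokines (-0.19) were at -0.11 without repletion replicate 4 or depletion replicate 1. Antigen presentation (-0.08) was at -0.12 without repletion replicate 4, and at -0.05 and -0.16 without depletion replicates 2 and 6. Endothelial genes (-0.06) were at 0.00 and -0.12 without repletion replicates 2 and 3, and at -0.11 without depletion replicate 1.

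The comparison of repletion with control asked whether muscle had returned to the control level. Slow fibre genes were higher in repletion than in control by a median of 0.29 (18 of 18 members), macrophage markers by 0.31 (21 of 23), and Schwann cell and nerve genes by 0.28 (18 of 20). Interferon response genes were higher by 0.17 (22 of 28) and immediate early genes by 0.22 (19 of 24). With an estimated correlation none of these 5 lists passed, the camera adjusted p being 0.817, 0.954, 0.945, 0.817 and 0.817 in the order named. The slow fibre score of repletion replicate 4 was -0.60, below all 4 controls, of which the lowest was -0.48. Glycolysis genes were not called (median -0.02, camera adjusted p = 0.822). For single genes, limma called 0 of 26387 probes (lowest adjusted p 1.00), with 142 higher and 83 lower at an unadjusted p under 0.05. These 225 are again below the share of 0.05 of the probes that unchanged probes give on average.

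Rnf128, an E3 ubiquitin ligase, had the smallest unadjusted p. It was not well above background on any control array and was on 3 of 4 repletion arrays. On the values used here this made it at least 1.52-fold higher in repletion, a bound that other settings do not keep. Its adjusted p from limma was 1.00 (chromosome X, 127366902 to 127366961). The difference of Rnf128 was -0.16 with normexp, 0.01 on the authors' values and -0.02 on the authors' values with slide as a block, so its direction is open. Fcgr3a, an Fc receptor of macrophages and natural killer cells, was higher by 0.94 ± 0.23 (chromosome 13, 86877181 to 86877240), the potassium channel Kcnj13 by 1.04 ± 0.27, the lymphocyte granzyme Gzmk by 0.50 ± 0.14 and Ppie by 0.45 ± 0.12. With normexp Fcgr3a differed by -0.004, Gzmk by -0.04 and Kcnj13 by 0.59, and on the authors' values by 0.28, 0.24 and 0.71. The median difference of all probes was itself -0.12 with normexp. The signs of Fcgr3a and Gzmk thus hung on the background correction, and their directions are left open. Lower were Cct8l2 (-1.33 ± 0.42, but -0.71 with normexp and -0.36 on the authors' values), the homeobox gene Hoxd8 (-0.72 ± 0.20) and Snx19 (-0.35 ± 0.10, with another of its probes at 0.05, and -0.17 on the authors' values). Yeats2 was lower too, but was well above background on 1 of 4 repletion arrays, so no size is given. Sval2 was not well above background on any repletion array and was at least 2.69-fold lower on the values used here. That bound does not hold with normexp, where Sval2 differed by -0.71, or on the authors' values, where it differed by -0.45.

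In the slow fibre list (adjusted p = 3.06e-06, and 0.817 with an estimated correlation), Atp2a2 was higher by 0.75 ± 0.35, Myh7b by 0.64 ± 0.32, Myh7 by 0.54 ± 0.27 and Tnnt1 by 0.35 ± 0.18. Macrophage markers (adjusted p = 0.000199, and 0.954 with an estimated correlation) included Aif1 at 0.62 ± 0.25, Cd53 at 0.48 ± 0.33 and Cd68 at 0.33 ± 0.25. Schwann cell genes (0.000199, and 0.945 with an estimated correlation) included Mbp at 1.98 ± 0.81, whose other probe gave 0.11. Interferon genes (0.00053, and 0.817 with an estimated correlation) included Oasl at 0.94 ± 0.57, but at -0.16 with normexp and 0.42 without control replicate 2, and it was well above background on 3 of 4 arrays of each group. Immediate early genes (0.00053, and 0.817 with an estimated correlation) included the orphan receptors Nr4a1, Nr4a2 and Nr4a3 at 0.66 ± 0.32, 1.33 ± 0.70 and 1.31 ± 0.83, and Fos at 0.65 ± 0.31. Antioxidant genes were higher by a median of 0.10 (18 of 26; 0.0272, and 0.817 with an estimated correlation), with haem oxygenase Hmox1 at 0.79 ± 0.29 and superoxide dismutase Sod1 at 0.33 ± 0.13. Ribosomal proteins were higher by 0.05 (46 of 55; 0.0102, and 0.954 with an estimated correlation) and tricarboxylic acid cycle genes were lower by a median of -0.09 (20 of 26; 0.025, and 0.954 with an estimated correlation), with Dlat at -0.34 ± 0.17. Within slides 1 and 2, the slides that held both diets, slow fibres gave 0.25 and 0.66, macrophages 0.30 and 0.10, Schwann cells 0.38 and 1.02, and interferon genes 0.23 and 0.16. Immediate early genes gave 0.35 and -0.10, antioxidant genes 0.13 and -0.06, ribosomal proteins -0.02 and 0.10, and the tricarboxylic acid cycle 0.12 and -0.23. With slide as a block the medians of these 8 lists were 0.33, 0.49, 0.45, 0.33, 0.09, 0.08, 0.05 and -0.09, and the scores lay on that side of the control mean on 4 of 4 repletion arrays for all but slow fibres and the tricarboxylic acid cycle, with 3 of 4. Vdr differed by -0.02 ± 0.45, Cyp27b1 by -0.03 ± 0.29, Notch1 by 0.02 ± 0.15, Fbxo32 by -0.18 ± 0.24 and Ppargc1a by -0.40 ± 0.28. With single arrays left out in turn the first 4 ran from -0.26 to 0.31, -0.21 to 0.16, -0.06 to 0.14 and -0.33 to -0.09, and without control replicate 1 Ppargc1a was at -0.07.

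Of the genes named from the 8 lists, Myh7b was at 0.39, Myh7 at 0.35 and Mbp at 1.04 without repletion replicate 2, and Nr4a3 was at 2.02 and 0.78 without control replicates 1 and 4. Slide as a block put Fos at 0.41, Nr4a2 at 0.80, Nr4a3 at 0.58 and Oasl at 1.52. Dlat was at -0.18 with normexp and -0.22 on the authors' values, and Nr4a1 was at 0.40 with depletion replicate 1 counted as repletion. Atp2a2 was at 0.48 without slides 2 and 3.

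Of the 43 lists, 8 passed, 7 higher and 1 lower, and 0 with an estimated correlation; the split was 16 and 0 with normexp and 6 and 0 with median centring. With slide as a block the calls of immediate early genes (camera adjusted p = 0.570), ribosomal proteins (0.108) and antioxidant genes (0.276) ended. Normexp, under which the median difference of all probes was -0.12, turned the Schwann cell median to -0.02. With normexp the immediate early median was 0.04 and the interferon median 0.08. Without repletion replicate 2 the Schwann cell median was 0.05 (0.277) and the tricarboxylic acid cycle had an adjusted p of 0.771. Without control replicate 4, adjusted p was 0.0927 for macrophages, 0.133 for immediate early genes, 0.523 for antioxidant genes and 0.150 for ribosomal proteins. Without control replicate 3 it was 0.138 for interferon genes, 0.645 for ribosomal proteins and 0.111 for the tricarboxylic acid cycle. Antioxidant genes were also lost without control replicate 1 (0.0704) or repletion replicates 1, 3 or 4 (0.0869, 0.150 and 0.0707), ribosomal proteins without repletion replicate 4 (0.305), and the tricarboxylic acid cycle without control replicate 2 (0.368) or repletion replicate 3 (0.243). The slow fibre call ended without slides 2 and 3 (0.0880).

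Beyond these, the tricarboxylic acid cycle was lost with normexp (camera adjusted p = 0.488), median centring (0.0597), replicate number as a block (0.0794), array weights (0.520) and the mean of a gene's probes (0.0510). Ribosomal proteins were lost with quantile normalization (0.224), median centring (0.0662), the authors' values (0.112), array weights (0.593) and the mean of a gene's probes (0.0642). Antioxidant genes were lost with quantile normalization (0.142) and on the authors' values (0.206), and Schwann cells with depletion replicate 1 counted as repletion (0.0516). Of 33 settings with the preset correlation, the call ended under 13 for ribosomal proteins, 12 for the tricarboxylic acid cycle, 11 for antioxidant genes, 5 for immediate early genes, 4 for Schwann cells, 2 for interferon genes, and 1 each for slow fibres and macrophages.

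Here too 1 array could shift a median. Slow fibres (0.29) were at 0.19 and 0.48 without repletion replicates 2 and 4. Schwann cells (0.28) were at 0.18 and 0.46 without control replicates 2 and 3, and at 0.45 without repletion replicate 4. Immediate early genes (0.22) were at 0.11 and 0.12 without control replicates 2 and 4, and at 0.14 and 0.11 without repletion replicates 1 and 4. Antioxidant genes (0.10) were at 0.05 without control replicate 1, and at 0.04 and 0.06 without repletion replicates 1 and 3. Ribosomal proteins (0.05) were at 0.03 without control replicate 3 and at 0.02 without repletion replicate 2 or 4, and the tricarboxylic acid cycle (-0.09) at -0.13, -0.04 and -0.05 without repletion replicates 1, 2 and 3.

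**Figure D4:**
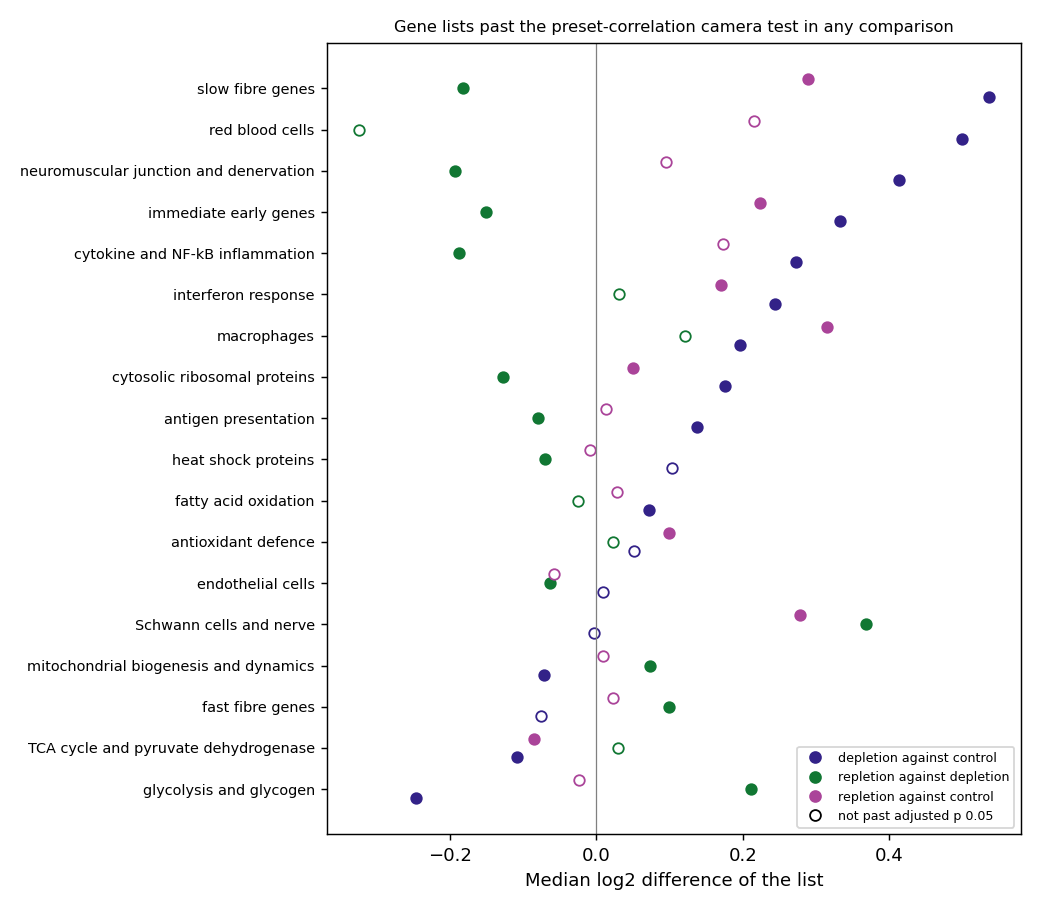
Median log2 difference of each of the 18 gene lists that passed the preset-correlation camera test in any comparison, with 1 colour per comparison; filled points are past an adjusted p of 0.05 and open points are not. Slow fibre genes stand at 0.54 in depletion against control, -0.18 in repletion against depletion and 0.29 in repletion against control.

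Whether repletion moved genes back was tested by the correlation, across genes, of the depletion minus control difference with the repletion minus depletion difference. Over all arrays r was -0.43 across 17431 genes, but the shared depletion arrays alone gave -0.40 in 50 simulations of unchanged, independent groups (range -0.42 to -0.38). The covariance was -0.033 against a simulated -0.057. Slide structure was left out of the simulation, so it gives no expected value for unchanged groups that share slides. With the 6 depletion arrays divided so that each difference used its own 3, the mean r over 20 divisions was 0.16 (SD 0.16, range -0.09 to 0.56). Genes with a missing value were left out of the divided correlations. Genes are not independent replicates, so no p is given. The mean r was 0.05 with slide as a block, -0.03 without depletion replicate 2, -0.01 without repletion replicate 3 and 0.27 without depletion replicate 4. A reversal across genes as a whole was not detected.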

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

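The tests of scaling and of diet as causes of the slide grouping, and of slide, of the choice among all lists and of splits within slides for the slow fibre result, were chosen only after the result was seen.

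An array was picked out when its gap to the nearest other array of its group exceeded Dixon's 95% critical share of the group's range. Of 477 groups of values 22 were picked out, and chance alone would pick out about 1 in 20. Repletion replicate 1 was picked out 5 times: Ppargc1a at -3.16 (nearest other -3.55), Ccl3 at -5.42 (-6.22) and Lyz2 at 4.07 (3.65) were the highest of the group, and Adipoq at -1.12 (0.21) and Fcgr3a at -6 (-5.35) the lowest. Depletion replicate 1 was picked out 4 times, with B2m at 5.44 (4.87) and Mt1 at 5.86 (3.92) highest and Idh3a at 0.69 (1.13) and Pvalb at 6.39 (7.37) lowest. Control replicate 3 was highest for Ccn1 at 3.35 (1.98) and Ankrd2 at 5.67 (4.39) and lowest for Or5b106 at -7.98 (-6.12). Control replicate 4 was highest for the myelin gene Mbp at 0.37 (-2.02), and repletion replicate 2 stood apart in the Schwann cell and nerve score at 1.33 (0). Single values were Chrna1 in depletion replicate 2 at 1.23 (2.19), Gyg1 in repletion replicate 4 at 1.94 (2.16), Cxcl10 in depletion replicate 5 at -1.66 (-3.97) and Gpd1 in repletion replicate 3 at 3.61 (4.26). Depletion replicate 6 was highest for Snx19 at -2.36 (-2.56) and lowest for the antigen presentation score at -0.33 (0.08). Oasl in control replicate 2 was lowest at -9.35 (-7.37), and the net signal of the negative controls in control replicate 1 was lowest at 14.68 (16.07).

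Arrays grouped by slide. Diet does not account for this, since it explained a share of 0.017 of the first component, and scaling between arrays does not either, since slide explained 0.999 of it after quantile normalization. Probe GC content is not settled: its rank correlation with the slide 2 difference was 0.178, between the values set for a cause and for none. Noise of dim probes is also not settled, because over the 13039 brighter probes slide explained 0.806, but between 0.525 and 0.990 with 1 array left out, a check added after the value was seen. The arrays also carry 5 distinct scan times, all on 1 date, over the 5 slides, so slide, scan time and any difference in handling cannot be told apart.

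Slow fibre genes were higher in depletion than in control. Slide as a block left the median at 0.54, and no single array carried it, the lowest median being 0.43 without depletion replicate 4. A fibre mix that differs between single muscles and not with diet was tested by splitting the 10 arrays in all 210 ways: 0.0286 of the splits gave this list a score difference as large. That prediction was too weak, since the list led all 43, and in a share of 0.505 of the splits some list stood as far out. Chance differences in fibre mix between muscles may therefore account for the result, and a diet effect on fibre type is not shown. Those splits also include ones that follow slide. Moving labels only within slides, with slide as a block, left 12 splits, too few for a share under 0.05; in 9 of them, the real one included, some list stood as far out as slow fibres did (2.02, highest other 5.02).

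Depletion replicate 1 carries labels of both diets. If it held a repletion muscle, its deviation should lie with the repletion arrays along the repletion minus depletion difference. Its correlation was -0.028, against -0.485 to -0.046 for repletion arrays and -0.00057 to 0.304 for other depletion arrays, so the axis placed the known repletion arrays on the wrong side of the depletion arrays. The test therefore cannot read the label, which stays unresolved.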

How the results depend on the processing

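The settings without slides, those joining slide with the label of depletion replicate 1, the authors' values with slide block, and slide block with the stricter list tests were chosen only after the result was seen. No probe passed in any of 102 probe tests over 34 settings; the lowest adjusted p was 0.194, in depletion against control without repletion replicate 4. Of the 206 named gene results 42 took the opposite sign under some setting. List calls depended most on the list test: in all 3 comparisons 0 lists passed with camera's estimated correlation, 0 with fry, and 0 with either under slide block. With an estimate camera also uses fewer degrees of freedom, and fry tests a list against no change and not against other genes, so neither 0 is put down to the correlation alone. Repletion against depletion gave 6 lists on the authors' values with slide block; repletion against control gave 16 with normexp and 4 with slide block without depletion replicate 1. With 1 array left out the counts ran from 9 (without control replicate 4) to 15 (without control replicate 1 or depletion replicate 3), from 5 (without repletion replicate 2) to 17 (without depletion replicate 1), and from 5 (without control replicate 3) to 9 (without control replicate 1 or 2), in the order of the report. Of the lists called in depletion against control, 5 were called under every setting with the preset correlation (slow fibre, ribosomal, immediate early, interferon, cytokine), and 0 in the other comparisons. None of these 5 passed the exact permutation test of list scores in that comparison once adjusted over lists. With 1 array left out, the reversal correlation ran from -0.034 (without depletion replicate 2) to 0.273 (without depletion replicate 4). It was -0.062 without slides 2 and 3 and 0.0068 with replicate number as a block. Over the 773 genes with an unadjusted p under 0.05, less those with a missing value, it was -0.494. These genes were selected on the same data.

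Directions that reversed were mostly in mitochondrial and proteasome lists and mostly hung on depletion replicate 1. Settings are given as normexp, moved (depletion replicate 1 counted as repletion), removed (without it), and each of the last with slide block. In depletion against control, OXPHOS complex I was -0.015 with normexp, 0.035 moved, 0.035 removed and 0.094 removed with block, and -0.091 without control replicate 1. OXPHOS complexes II to V were -0.007, 0.063, 0.063 and 0.106 in the same order, and -0.076 without control replicate 1, and with block and removal proteasome genes were -0.093 and the tricarboxylic acid cycle 0.012. In repletion against depletion, moved, removed, removed with block and moved with block, proteasome genes were 0.133, 0.069, 0.095 and 0.112 and OXPHOS complex I -0.175, -0.073, -0.088 and -0.145; with other single arrays left out they reached -0.025 (without depletion replicate 2) and 0.06 (without repletion replicate 3). The tricarboxylic acid cycle was -0.105 moved, -0.07 removed with block and -0.098 moved with block, fast fibres -0.04 moved and 0.001 moved with block, and cytokines -0.043 moved. OXPHOS complexes II to V were 0.193 without slides 2 and 3, and tendon genes 0.452 without repletion replicate 4 and -0.322 without repletion replicate 1. In repletion against control, normexp gave 0.013 for OXPHOS complex I, 0.009 for complexes II to V and -0.057 for the tricarboxylic acid cycle; without slides 2 and 3 the last 2 were 0.076 and 0.057. Fibroblast and matrix genes were 0.187 without control replicate 1 and -0.138 without control replicate 2, and tendon genes 0.365 without repletion replicate 4 and -0.395 without repletion replicate 1. Some of these reversed in camera's direction and not in the sign of the median, as normexp shifts all genes; otherwise the cause was not tested. Dim probes limit the depth: the lowest share of spots well above background was 82.8%.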

Other observations

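The splits by adjusted p and the splits within slides were counted only after the result was seen.

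Several gene groups chosen for their place in vitamin D biology passed the test in no comparison. In depletion against control, repletion against depletion and repletion against control, in that order, vitamin D metabolism and receptor genes had medians of -0.11, 0.08 and -0.03 (camera adjusted p = 0.411, 0.234 and 0.995), Notch signalling had medians of 0.01, 0.02 and 0.02, atrophy and ubiquitin ligase genes -0.01, 0.09 and 0.00, and adipocyte genes 0.03, -0.12 and -0.03. With this test a difference in them is neither shown nor excluded (lowest adjusted p 0.165, adipocytes in repletion against depletion). Satellite cell and matrix genes did not pass either. In depletion against control their medians were 0.20 and -0.23 (camera adjusted p = 0.0546 each, and 0.387 and 0.955 with an estimated correlation; exact p of the score 0.210 and 0.486). In repletion against depletion matrix genes had a median of 0.14 (0.0721, and 0.818 with an estimated correlation) and circadian clock genes 0.21 (0.0956, and 0.575).

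Whether the counts exceed what other groupings of the same arrays give was tested on 26078 probes without missing values. In each count below the real split is included. For lists, 28 of 100 splits reached the 13 of depletion against control (highest other 21). In repletion against depletion 47 of 100 reached 12 (19), and in repletion against control 17 of 35 reached 8 (17). For unadjusted probe counts, 59 of 100 reached 957 (highest other 4813), 92 of 100 reached 375 (3712) and 33 of 35 reached 224 (4017). Chance cannot be excluded for these counts. For adjusted counts all 100, 100 and 35 splits reached the 0 observed, as any grouping must, so this says nothing on chance; the highest others were 30, 540 and 1. The split with 4813 probes set the arrays of slides 2, 3 and 4 against those of slides 1 and 5, and the split with 540 set slide 3 with depletion replicate 1 against the rest, which points to a structure of the samples by slide. The same was therefore tested with labels moved only within slides and slide as a block, where 0 probes passed in the real splits and at most 1 in another, and the real split counts among those that reach its value. In repletion against depletion, 16 of 24 splits reached 904 unadjusted probes (highest other 3171) and 21 of 24 reached 9 lists (18), so chance cannot be excluded. Depletion against control had 12 such splits and repletion against control 6, too few for a share under 0.05. In depletion against control 6 of 12 reached 1259 probes (highest other 2656) and 8 of 12 reached 10 lists (19), and in repletion against control 5 of 6 reached 523 probes (1609) and 6 of 6 reached 8 lists (14).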
